A study of Mus musculus with 13 samples.

How the data were processed

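RNA from 13 primary cultures of neonatal mouse dermal fibroblasts was analysed, 6 from WT and 7 from Fbn1 G234D homozygous animals, in 2 sets. Per the labels, total RNA was purified on columns, checked on a bioanalyzer and made into stranded libraries, and the submitters' processing notes name the genome build mm10. The aligner, the counting tool and the annotation release are not given in the sources used here. The values were TPM made by the authors, per the file headers, and each library's values summed to 1000000 over the same 25655 genes. TPM carry no read totals, so the depth of each library is unknown and no counting interval could be given. Gene symbols and identifiers were those the set 2 tables pair with each other, and 25600 identifiers matched GENCODE release M21, which gave coordinates on mm10. Xist and Tsix were not among the genes of these tables.

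The design fixed before the data were examined assumed read counts and gave a fallback for other units, which was used: TPM were transformed to log2(TPM + 1) and tested with the moderated linear models of limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust empirical Bayes. The filter was set once the unit was known. Genes were kept at 1 TPM or more in at least 6 libraries over both sets, 4 in set 1 and 2 in set 2, the size of the smaller genotype group. The comparisons were G234D minus WT over both sets with the set as a covariate, within set 1, within set 2, and the set by genotype interaction. The p values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes at an adjusted p under 0.05 were called. The median SE of the log2 difference was 0.062 over both sets, 0.080 in set 1 and 0.087 in set 2, and these set the precision. Differences of the 2 sets were correlated over genes, with exact permutation p values from all 700 relabelings of genotype within the sets.

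The 40 gene lists were fixed before the data were examined. They covered matrix components, collagen processing, integrins, signalling, proliferation, stress, metabolism, fibroblast subtypes, positional genes and markers of other cell types. Lists were tested at 5 or more tested members, which left 38; erythroid and sex-linked genes had 0 tested members over both sets. Aldoa and Ddit3 were not matched to a single entry and were left out. Lists were tested with camera at a preset correlation of 0.01, which ranks a list against other genes, and again with an estimated correlation and with fry, which tests whether the members move on balance one way and compares them with no other genes.

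Genes were named by a rule also fixed before the data were examined: Fbn1; the 10 smallest p in each direction among genes called over both sets, or the 5 smallest p in a direction where none was called; called genes of each set (the 5 smallest p in each direction) and of the interaction (the 3 smallest p); up to 4 members of each list with the smallest p; and Xist and Ddx3y. Clone-like and unnamed symbols were counted and not named. Genes outside the rule are said to be so where they appear. Some genes that the rule would name are not reported here. Ddx3y is given with the closing observations.

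To check pairing, each library's deviations from its group mean were correlated between WT and G234D cultures with the same replicate number. The correlations were 0.314, 0.236, 0.244 and 0.214 in set 1, all over the limit of 0.1 set in advance, and −0.155 and 0.0138 in set 2. The correlations of set 1 also followed the animal groups: 2 of 4 G234D cultures correlated best with their own number, while W1 with M2 gave 0.397 and M4 with W3 0.440. The replicate number was run as a block; the numbers are shared by label, and no label says that they mark a litter or day. Values with the block are printed where they change a call over both sets or in set 1, and as counts in set 2, where the numbers did not pair the cultures. After the data were examined, set 1 was also divided by animal number (6755 to 6993, 7112 to 7115). Genotype was compared within each group and with the group as a block. This division joined W1 (6755) to the animals 6989 to 6993, from which the blocks fixed in advance had kept it apart.

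The models were tested on simulated data with 50 genes at each of 4 fold sizes. The changed genes were drawn from those at higher mean levels only, and the change was added on the log2(TPM + 1) scale. The recovered shares therefore do not cover genes near the filter of 1 TPM. Over both sets 70% of genes changed 1.25-fold and 98% of those changed 1.5-fold were recovered, with 4.28% of calls on unchanged genes. In set 1 the shares were 48% and 92% (5.65% of calls on unchanged genes), and in set 2 they were 54% and 92% (10.4%). Simulated cultures varied without the shared structure of real ones, so the recovered shares are upper limits and the shares of calls on unchanged genes are not.

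Alternatives to the filter (none, or 10 TPM), the robust step, the set term, a replicate block, an animal number block, a Y-linked covariate, an inverse-variance mean of the sets and each library left out were fixed before the data were examined. Pseudocounts of 0.1 and 5, median-of-ratios scaling, quantile normalization, no trend, array weights, the block of 2 animal-number groups and the fit without M1 and M2 were added after seeing the data. Alternatives that need counts were not run: no edgeR, DESeq2, voom or surrogate variable fit was made. The same libraries were also split in other ways, to see how often as many genes or lists passed. There were 100 splits over both sets and all 35 in set 1. The real split is 1 of these and is included in every count of splits. Differences of list means were also given 95% intervals with the cultures as replicates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.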

Results

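The series asked whether mice homozygous for the G234D allele of Fbn1 have dermal fibroblasts that differ in themselves, in particular in the genes of the extracellular matrix. Fbn1 encodes fibrillin-1, the secreted glycoprotein that builds the microfibrils of the dermis and of elastic fibres. RNA was sequenced from stranded libraries of total RNA of 13 primary cultures of neonatal dermal fibroblasts. Set 1 held 4 wild-type (WT) cultures, W1 to W4, and 4 homozygous cultures, M1 to M4. Set 2 held 2 WT cultures, W5 and W6, and 3 homozygous cultures, M5 to M7. After the data were examined, set 1 was divided by the order of the animal numbers in the titles. The earlier animals were W1, W2, M1 and M2, and the later animals were W3, W4, M3 and M4. The number of W1 lies far below those of M1, M2 and W2, and the blocks fixed in advance kept it apart. The numbers alone therefore do not place W1 with M1, M2 and W2. Between 11741 and 12042 genes reached 1 TPM in a library. The values were TPM, so the read depth behind them is unknown. Differences are homozygous minus WT on the log2(TPM + 1) scale, which understates differences of genes at low levels.

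Fbn1 itself (ENSMUSG00000027204, minus strand of chromosome 2 from 125300594 to 125507993, build mm10) was not called as different between the genotypes. In set 1 it stood at 491 ± 42.8 TPM in WT (SD, n = 4) and 542 ± 50.2 TPM in G234D cultures (SD, n = 4). In set 2 it stood at 405 ± 8.03 TPM in WT (SD, n = 2) and 452 ± 32.2 TPM in G234D cultures (SD, n = 3). Over both sets the log2 difference was 0.15 (SE 0.058, 95% interval 0.023 to 0.27, adjusted p = 0.742), a 1.11-fold value, and 6 of the 7 G234D cultures lay above the WT mean of their set. The difference was 0.16 in the earlier animals, 0.13 in the later animals and 0.15 in set 2. A point mutation leaves the transcript in place, so this level does not check the genotype labels.

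Over both sets, which address the effect of genotype common to all cultures, limma called 0 of 11942 genes, with a lowest adjusted p of 0.449. At unadjusted p under 0.05 there were 769 genes, 504 higher and 265 lower in G234D, where 597 would be expected by chance. The 5 genes with the smallest p among those higher were Ctsh, a lysosomal cysteine protease, Slc7a8, a neutral amino acid transporter, Tmed4, a cargo protein of the early secretory pathway, Nrip2, a nuclear receptor interacting protein, and Cpz, a carboxypeptidase found in the matrix. Ctsh stood at 69.6 ± 4.04 TPM in WT and 88.6 ± 5.34 TPM in G234D cultures of set 1 (SD, n = 4 each), a log2 difference over both sets of 0.28 (SE 0.051). The differences of the other 4 genes were 0.52, 0.14, 0.46 and 0.60. The 5 genes on the lower side were Bok, a BCL2 family member, with a difference of −0.25 (SE 0.047), Epha3, an ephrin receptor, at −0.47, Pmepa1, a transforming growth factor beta (TGF-beta) target that dampens Smad signalling, at −0.13, Shkbp1 at −0.21 and Cdc20, an activator of the anaphase-promoting complex, at −0.18. The first 9 of these 10 genes lay on the same side of the WT mean of their set in 7 of 7 G234D cultures, and Cdc20 in 6 of 7. Their choice by a small p favours such a count. Their adjusted p values ran from 0.449 to 0.696.

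Matrix genes lay on both sides of 0 over both sets. In the 8 lists for matrix components, their processing and their receptors, 201 genes were tested and limma called 0, with 20 at unadjusted p under 0.05. Of these 201 genes 118 had positive and 83 negative values. For 160 of them (79.6%) the 95% interval of the difference lay within 1.5-fold in either direction. Microfibril and elastic fibre genes had 16 positive and 14 negative members (mean 0.023, adjusted p = 0.672), among them the fibulin gene Efemp1 at 0.44 (SE 0.19), Mfap3 at 0.12 and Ltbp3, which encodes a latent TGF-beta binding protein, at 0.15. Fibrillar collagens had 3 positive and 7 negative members (mean −0.032, adjusted p = 0.184), with Col5a3 at −0.19 and below the WT mean of its set in 7 of 7 G234D cultures, Col27a1 at −0.16 and Col1a1 at −0.087. The list passed without M3 (adjusted p = 0.0303), M5 (0.0276) or M7 (0.00994). Without M1 Col1a1 was at −0.045 and Col27a1 at −0.10. Col27a1 differed by −0.53 in the earlier animals, 0.025 in the later animals and −0.011 in set 2. Other collagens had 8 positive and 10 negative members (mean 0.019, median −0.022, adjusted p = 0.616 with a downward sign). Col14a1, a collagen on the surface of fibrils, was the 1 member of that list past the test adjusted over the list alone, against 0 over all genes, with a difference of 0.56 (SE 0.15). It stood at 8.98 ± 0.388 and 17.2 ± 3.81 TPM in WT and G234D cultures of set 1 and at 9.64 ± 1.01 and 10.3 ± 1.75 TPM in those of set 2. Col18a1, a basement membrane collagen, was at 0.49 (SE 0.18), made up of 0.78 in set 1 and 0.027 in set 2.

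Genes that process collagen had 15 positive and 10 negative members (mean 0.038, adjusted p = 0.221). Fkbp14, a prolyl isomerase of the endoplasmic reticulum that acts on collagen, was above the WT mean of its set in 7 of 7 G234D cultures at 0.19 (SE 0.042) and was the 1 member past the test adjusted over the list alone, against 0 over all genes. P4ha2, a prolyl hydroxylase subunit, was at 0.14 and P3h3 at 0.076. Proteoglycans had 15 positive and 11 negative members (mean 0.037, adjusted p = 0.395), with Podnl1 at −0.58, Podn at 0.30, Gpc6 at 0.15 and Sdc4 at 0.15. Adhesive and matricellular glycoproteins had 24 positive and 11 negative members (mean 0.039, adjusted p = 0.395), with fibronectin (Fn1) at 0.20, Mgp, an inhibitor of calcification, at 0.49 and Npnt, an integrin ligand, at −0.34. Matrix proteases and inhibitors had 31 positive and 12 negative members (mean 0.078, adjusted p = 0.287), with the metalloprotease inhibitor Timp3 at 0.31, Mmp15 at 0.44 (1.33 in the earlier animals, 0.086 in the later animals and −0.0056 in set 2) and Adamts16 at −0.36 (−1.10, 0.20 and −0.22). Integrins had 6 positive and 8 negative members (mean 0.0041, median −0.0079, adjusted p = 0.323 with a downward sign), with Itgb5 at −0.092 and the collagen receptor subunit Itga11 at −0.27.

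**Figure D1:**
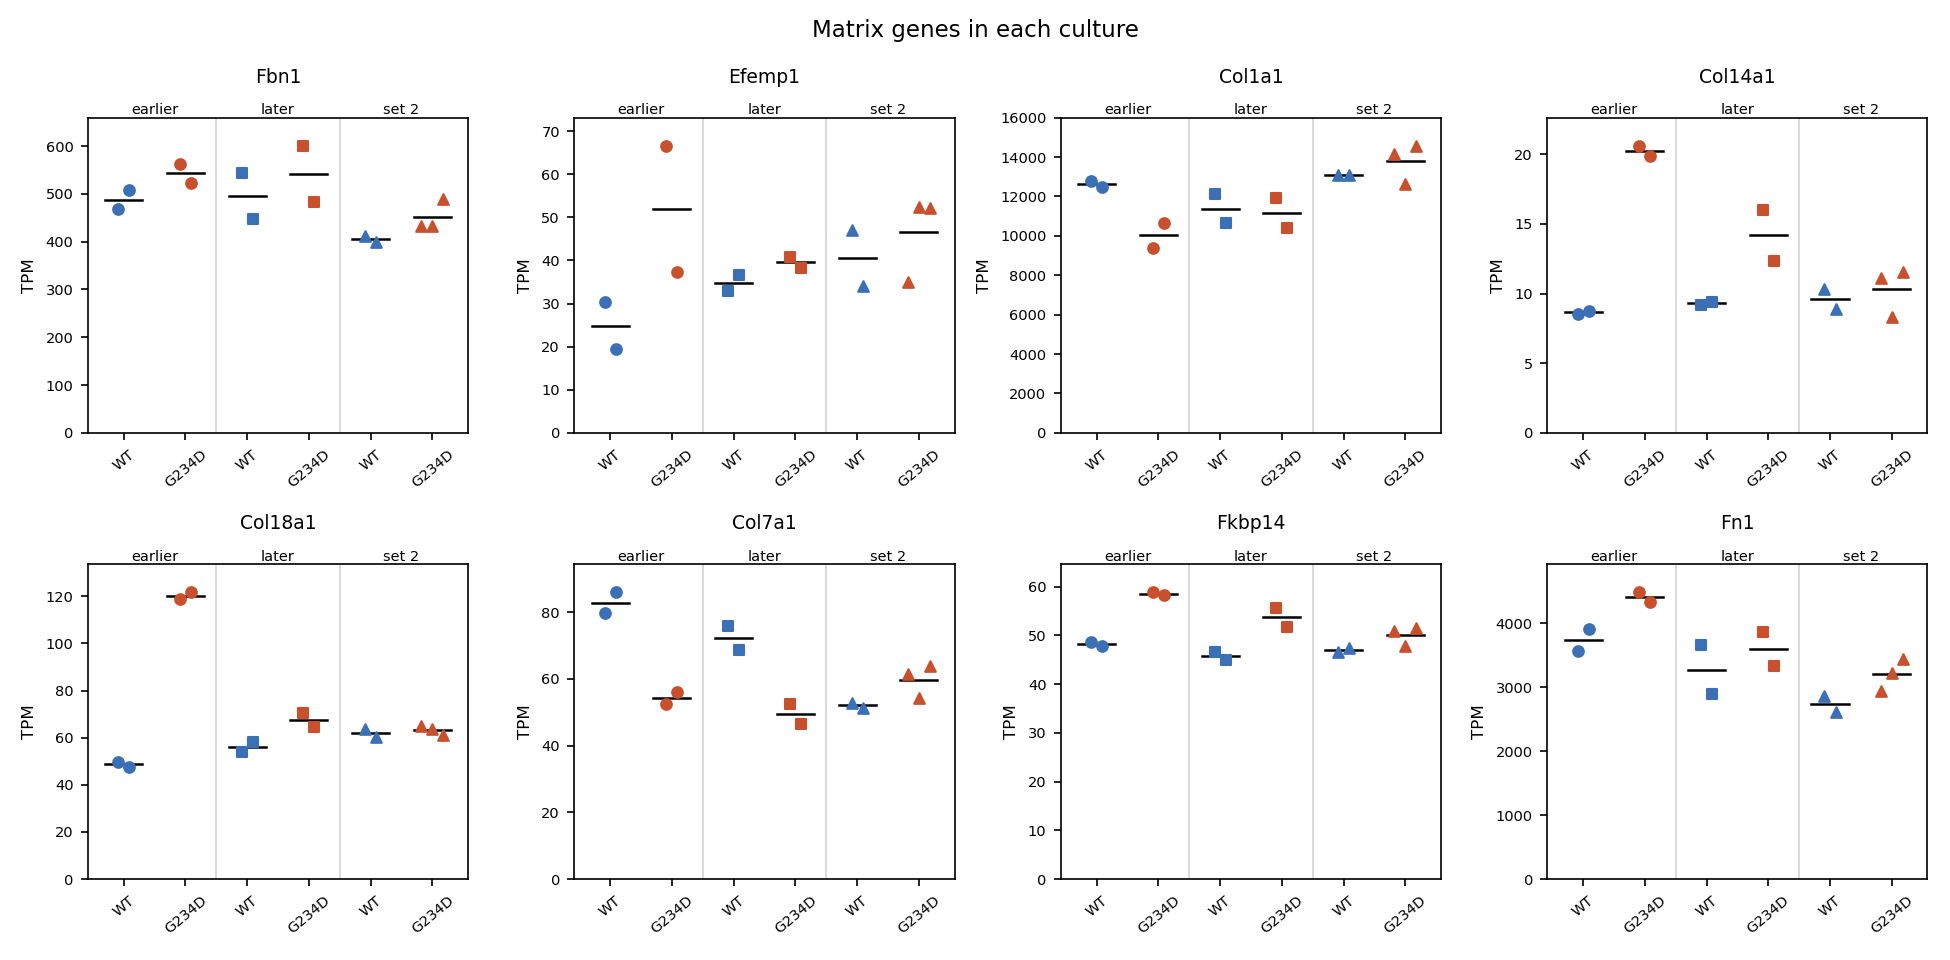
TPM (y axis, from 0) of 8 matrix genes in each of the 13 cultures by genotype (x axis), in the earlier and later animals of set 1 and in set 2; bars are group means. Col14a1, Col18a1 and Col7a1 part the genotypes in the earlier animals (log2 differences 1.14, 1.29 and −0.60); the differences are 0.55, 0.26 and −0.54 in the later animals and 0.079, 0.027 and 0.19 in set 2.

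Of 38 gene lists tested over both sets with the preset correlation, 10 passed, 5 upward and 5 downward, and 0 passed with an estimated correlation (lowest adjusted p = 0.684) or by fry (lowest adjusted p = 0.678). The largest upward shifts were in markers of cells other than fibroblasts. Skeletal muscle genes were positive in 14 of 14 members (mean 0.70, adjusted p = 3.3e-05, and adjusted p = 0.684 with an estimated correlation), with Tnnc2, a troponin of fast muscle, at 1.04 and Myh3, an embryonic myosin, at 0.86. Tnnt3 and Myh8 were at 0.72 and 0.54. Without M1 Myh3, Tnnt3 and Myh8 were at 0.54, 0.45 and 0.36. Macrophage and leukocyte genes were positive in 13 of 13 members (mean 0.48, adjusted p = 9.0e-05, and adjusted p = 0.684 with an estimated correlation), with C1qa at 0.76, Laptm5 at 0.61, Cd68 at 0.49 and Adgre1 at 0.43. Melanocyte and Schwann cell genes were positive in 8 of 9 members (mean 0.55, adjusted p = 0.00622, and adjusted p = 0.684 with an estimated correlation), with Ngfr at 1.08, Cdh19 at 0.89, Sox10 at 0.86 and Foxd3 at 0.79. M1 and M2 lay highest above the WT mean of their set. The muscle list lay 2.28 and 1.68 above the WT mean of set 1 in these 2 cultures, and the genotype difference of the members tested over both sets was 2.04 in the earlier animals, −0.27 in the later animals and 0.41 in set 2. For the macrophage list these differences were 0.97, 0.21 and 0.30, and for the glial and melanocyte list 1.51, 0.25 and 0.0022. Without M1 and M2 the adjusted p was 0.736 for muscle, 0.273 for macrophage and 0.0236 for melanocyte and Schwann cell genes. For the last of these it was 0.0702 without W1, 0.0555 without W2 and 0.10001 with no filter on low TPM. The fit without M1 and M2 leaves only later animals among the G234D cultures of set 1, against WT cultures of both animal groups.

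Interferon response genes were positive in 32 of 38 members (mean 0.16, adjusted p = 0.0126, and adjusted p = 0.711 with an estimated correlation), with Irf9, a transcription factor of the pathway, at 0.24 (0.14 without M1), Gbp6 at 0.27 and Ifit2 at 0.16. The list differed by 0.60 in the earlier animals, −0.0099 in the later animals and −0.063 in set 2, so it moved with the macrophage, muscle and glial markers of M1 and M2. Its adjusted p was 0.686 without M1, 0.0615 without M2, 0.0696 without W2, 0.0503 with the animal numbers as a block and 0.102 with Y-linked expression as a covariate, and without both M1 and M2 the list shifted the other way (adjusted p = 0.0332). Adipogenic genes were positive in 16 of 19 members (mean 0.14, adjusted p = 0.0138, and adjusted p = 0.684 with an estimated correlation), and the list mean lay above every WT culture of its set in 7 of 7 G234D cultures. Klf15, a transcription factor of fat cells, was at 0.34 and the fatty acid receptor Cd36, which macrophages also express, at 0.67 (0.44 without M2). Cd36 differed by 1.30 in the earlier animals, 0.13 in the later animals and 0.59 in set 2. The adipogenic list differed by 0.14, 0.22 and 0.054 in the earlier animals, the later animals and set 2. Its adjusted p was 0.0709 without W2, 0.0606 without M3, 0.191 without M4, 0.113 with no filter and 0.129 with a stricter filter.

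Proliferation genes were negative in 34 of 40 members (mean −0.053, adjusted p = 1.6e-06, and adjusted p = 0.684 with an estimated correlation), with the mitotic kinase Aurka at −0.12 and the mitotic kinesin Kif20a at −0.13. The list differed by −0.15 in the earlier animals, −0.024 in the later animals and 0.0059 in set 2. Cholesterol and lipid synthesis genes were negative in 27 of 28 members (mean −0.072, adjusted p = 3.5e-05, and adjusted p = 0.711 with an estimated correlation), with Fdps at −0.19 and Mvd at −0.18, both enzymes of the sterol pathway. The list differed by −0.12 and −0.19 in the earlier and later animals and by 0.070 in set 2, and without M1 and M2 its adjusted p was 0.260. Contractile and cytoskeletal genes were negative in 21 of 23 members (mean −0.056, adjusted p = 0.00224, and adjusted p = 0.711 with an estimated correlation), with Lmod1 at −0.21 and the myosin light chain gene Myl9 at −0.11 (−0.058 without M4). That list differed by 0.077, −0.23 and −0.016 in the earlier animals, the later animals and set 2, and its adjusted p was 0.0606 without M3 and 0.420 without M4. TGF-beta response genes were negative in 20 of 29 members (mean −0.020, adjusted p = 0.0103, and adjusted p = 0.684 with an estimated correlation). Pmepa1 was the 1 member past the test adjusted over the list alone, against 0 over all genes, and Lmo7 was at −0.26. The adjusted p of this list was 0.125 without M4 and 0.112 after quantile normalization, and it differed by −0.0064, −0.072 and 0.011 in the earlier animals, the later animals and set 2.

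Ribosomal protein genes were negative in 57 of 74 members (mean −0.015, adjusted p = 0.0431, and adjusted p = 0.777 with an estimated correlation), with Rpl24 at −0.056 (−0.086 without M4) and Rps27 at 0.093 (0.041 without M4). The list differed by −0.093, 0.13 and −0.067 in the earlier animals, the later animals and set 2. Without W3, W4, M6, M7, W5 or W6 its adjusted p was 0.120, 0.361, 0.147, 0.484, 0.0506 and 0.825, and the direction turned upward without M1 (adjusted p = 0.898), without M2 (0.871) and without both (2.5e-05). The adjusted p was also over 0.05 with a stricter filter (0.0878), the replicate block (0.353), the Y-linked covariate (0.844), median-of-ratios scaling (0.0602) and quantile normalization (0.956).

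The remaining 28 lists did not pass over both sets. TGF-beta ligands, receptors and Smads had 16 positive and 12 negative members (mean 0.0023, median 0.016, adjusted p = 0.482 with a downward sign), with Acvr2b at −0.27 and Tgfb1 at −0.095. BMP response genes had 15 negative members of 22 (adjusted p = 0.129), with the antagonist Chrd at 0.38 and the target Id1 at −0.20. Targets of YAP and MRTF-SRF had an adjusted p of 0.340, the Wnt pathway 0.482, and Hedgehog, Notch and FGF signalling 0.835, with Fgf7 at 0.28; the last of these had a positive mean (0.024) and median (0.0066) and a downward sign. Genes of p53 and senescence were positive in 18 of 23 members (adjusted p = 0.184, and 0.0372 without M3), with Gadd45a at 0.16 and Btg2 at 0.22. Chemokine and cytokine genes were positive in 22 of 28 members (adjusted p = 0.0909), with Lif at 0.35 and Il6 at 0.30, and passed without M3 (0.0173), M4 (0.0331), W3 (0.0188), W4 (0.0230) or W6 (0.0150). The unfolded protein response had an adjusted p of 0.367, with Atf6 at 0.14 and the chaperone gene Dnajb9 at 0.12 and above the WT mean in 7 of 7 G234D cultures. Hypoxia and glycolysis genes had an adjusted p of 0.889. Oxidative phosphorylation genes were negative in 31 of 49 members (adjusted p = 0.0935), with Ndufa3 at 0.12, and passed downward without W1 (0.0179), M1 (0.00913), M4 (0.00693), W3 (0.0200) or M5 (0.0190) and with the animal numbers as a block (0.0144). Immediate early and stress genes were positive in 24 of 31 members (adjusted p = 0.340), and the metallothionein gene Mt2, at 0.41 (SE 0.10), was the 1 member past the test adjusted over the list alone, against 0 over all genes; the heat shock gene Hspa1a was at −0.32.

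Lists for fibroblast subtypes and positions gave adjusted p values of 0.151 for papillary fibroblasts, 0.129 for reticular and hypodermal fibroblasts, 0.446 for the dermal papilla and 0.0909 for adult dermal fibroblast identity, whose members were negative in 12 of 16. The identity list passed without W1 (0.0292), M3 (0.0320) or M4 (0.0309) and the reticular list without M6 (0.0305) or W5 (0.0450), and the papillary list passed with the animal numbers as a block (0.0490) and with the 2 animal groups as a block (0.0448). Col14a1 was also the 1 member of the reticular list past the test adjusted over the list alone, against 0 over all genes. The dermal papilla list, with Sox2 at 0.88 (2.31, −0.20 and 0.59 in the earlier animals, the later animals and set 2), had a mean of 0.0018, a median of −0.068 and a downward sign. The values were 0.367 for chondrogenic and osteogenic genes, 0.142 for Hox and Tbx genes, 0.799 for keratinocyte genes, 0.668 for endothelial genes and 0.142 for pericyte and smooth muscle genes. The last of these passed downward with the animal numbers as a block (0.00838), with the 2 animal groups as a block (0.0404), without M1 (0.0405) and without M2 (0.0133). Keratinocyte genes (mean 0.049, median 0.19) and endothelial genes (mean 0.024, median 0.037) had a downward sign. In the keratinocyte list the epithelial gene Sfn, at −0.51 (SE 0.15), was the 1 member past the test adjusted over the list alone, against 0 over all genes.

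**Figure D2:**
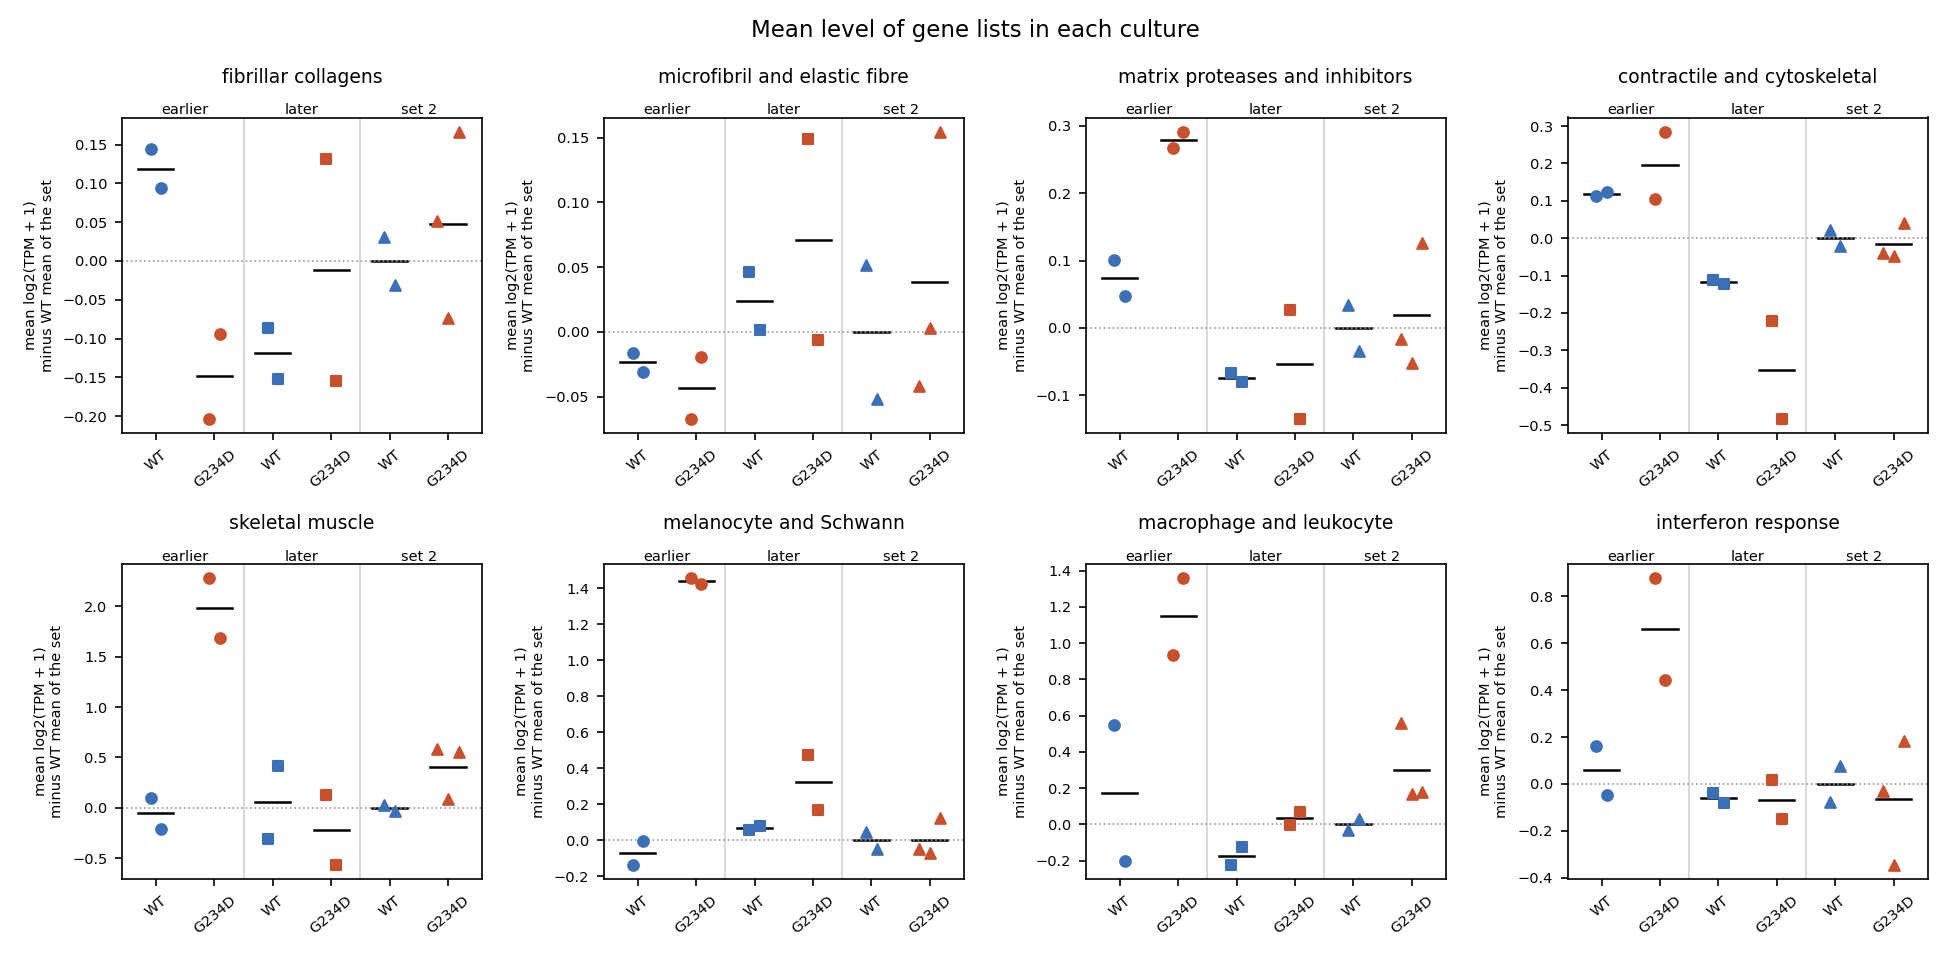
Mean log2(TPM + 1) of 8 gene lists in each of the 13 cultures, minus the WT mean of the set (y axis), by genotype (x axis), for the earlier and later animals of set 1 and for set 2; bars are group means. Relative to the WT mean of the set, M1 and M2 lie highest in the muscle (2.28 and 1.68), melanocyte and Schwann (1.46 and 1.42), macrophage (0.94 and 1.36) and interferon (0.88 and 0.44) lists. W1 (0.55) and M5 (0.56) are raised in the macrophage list too. Before subtraction the interferon level is 4.07 in W5 and 4.22 in W6, above M1 (3.98) and M2 (3.54). The macrophage level of M5 (3.18) then lies between M1 (2.87) and M2 (3.29).

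Within set 1, 4 cultures of each genotype were compared, and Col7a1 was among the genes that shared the lowest adjusted p. Col7a1, which encodes the collagen of anchoring fibrils, stood at 77.6 ± 7.24 TPM in WT and 51.9 ± 4.01 TPM in G234D cultures (SD, n = 4 each), a log2 difference of −0.57 (SE 0.078, adjusted p = 0.182). With the replicate numbers as a block it was the 1 gene called (SE 0.041, adjusted p = 0.0410), and with the 2 groups of animal numbers as a block its adjusted p was 0.0283. With the latter block its adjusted p was over 0.05 without W1 (0.0804), M1 (0.146), M2 (0.0630), W2 (0.196) or W3 (0.234), at differences between −0.58 and −0.54. The difference was −0.60 in the earlier and −0.54 in the later animals, and in set 2 it was 0.19, from 52.1 ± 1.13 TPM in WT to 59.8 ± 5.02 TPM in G234D cultures. Without a block limma called 0 of 11905 genes, with 721 at unadjusted p under 0.05, 373 higher and 348 lower. Adjusted over the list alone, 5 other collagens passed, 3 of them higher, against 0 over all genes, and 5 melanocyte and Schwann cell genes passed, all higher, against 0 over all genes.

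Of the 38 lists 12 passed in set 1 with the preset correlation, 7 upward and 5 downward, and 0 with an estimated correlation. Fibrillar collagens shifted downward (mean −0.11, adjusted p = 0.0359, and adjusted p = 0.725 with an estimated correlation), with Col1a1 at −0.18. The adjusted p was 0.0493 with the replicate block, 0.0614 with the animal groups as a block, 0.132 without W1, 0.257 without M1, 0.0999 without M2, 0.111 without W2 and 0.137 without M4. Reticular and hypodermal fibroblast genes shifted upward (mean 0.20, adjusted p = 0.00720, and adjusted p = 0.573 with an estimated correlation), as did p53 and senescence genes (mean 0.093, adjusted p = 0.0408, and adjusted p = 0.725 with an estimated correlation), the latter not without W1 (0.0517), M1 (0.372), M2 (0.262), W3 (0.0914) or W4 (0.10002). Cholesterol synthesis (mean −0.16), proliferation (−0.088), contractile (−0.079) and TGF-beta response genes (−0.039) shifted downward, with adjusted p values of 8.3e-10, 4.3e-07, 0.0334 and 0.0175, against adjusted p values of 0.611, 0.665, 0.792 and 0.573 with an estimated correlation. Of these, the contractile list did not pass without W1 (0.120), W2 (0.223), M3 (0.493) or M4 (0.936), and the TGF-beta response list without M4 (0.193) or W3 (0.0592). Interferon (mean 0.31), muscle (0.85), melanocyte and Schwann (0.88), macrophage (0.64) and adipogenic genes (0.20) shifted upward, with adjusted p values of 5.4e-06, 8.1e-05, 2.0e-04, 0.00182 and 0.00720, against adjusted p values of 0.665, 0.725, 0.573, 0.665 and 0.573 with an estimated correlation. The adipogenic list did not pass without W2 (0.0844) or M4 (0.137). The replicate block kept all 12 and added matrix proteases upward (adjusted p = 0.0220, 0.0586 without the block), papillary fibroblast genes downward (0.0277, 0.117 without) and keratinocyte genes downward (0.0493, 0.0662 without), each with an adjusted p of 0.513 with the block and an estimated correlation.

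The genotype differences of set 1 were unlike in its 2 groups of animals, a division made after the values were seen. In the earlier animals, M1 and M2 against W1 and W2, limma called 976 of 12077 genes, 604 higher and 372 lower in G234D. W2 alone of these cultures lacked Y-linked expression (Ddx3y at 0 TPM, against 58.3 in W1, 61.9 in M1 and 54.3 in M2). Genotype and Y-linked expression were therefore not balanced in this comparison. Mitochondrial transcripts made up 5.67% and 5.21% of TPM in M1 and M2 against 4.59% and 4.53% in W1 and W2, and ribosomal protein transcripts 13.1% and 13.2%, the lowest shares of the 13 libraries. In the later animals, M3 and M4 against W3 and W4, it called 1 gene, with 1071 at unadjusted p under 0.05. The count in the earlier animals was 376 without W1, 256 without W2, 526 without M1 and 1514 without M2, where the lone culture of a genotype was assumed to vary like the others. Among the earlier animals 7 of 9 fibrillar collagens were called lower and 0 higher (mean −0.31 of these 9), with Col1a1 at −0.33. Over the members tested over both sets this list differed by −0.27 in the earlier animals, 0.11 in the later animals and 0.048 in set 2. Of other collagens 6 of 18 members were called higher and 6 lower, with Col18a1 at 1.29. Of matrix proteases and inhibitors 16 of 43 members were called higher and 3 lower. Proliferation genes were called lower in 7 of 40 members (list mean −0.15), and interferon genes were called higher in 11 of 36. In these same cultures 16 of 17 skeletal muscle genes and 6 of 9 melanocyte and Schwann cell genes were called higher. Among the latter were Ngfr, the nerve growth factor receptor gene, at 2.63 and Sox10 at 2.31. Of 15 macrophage and leukocyte genes 2 were called higher and 1 lower, and of 16 fibroblast identity genes 2 were called higher and 6 lower. Of the 976 genes, 372 of the 900 tested in the later animals (41.3%) and 569 of the 918 tested in set 2 (62.0%) had the same direction there, and 0 and 1 of them were called there too.

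**Figure D3:**
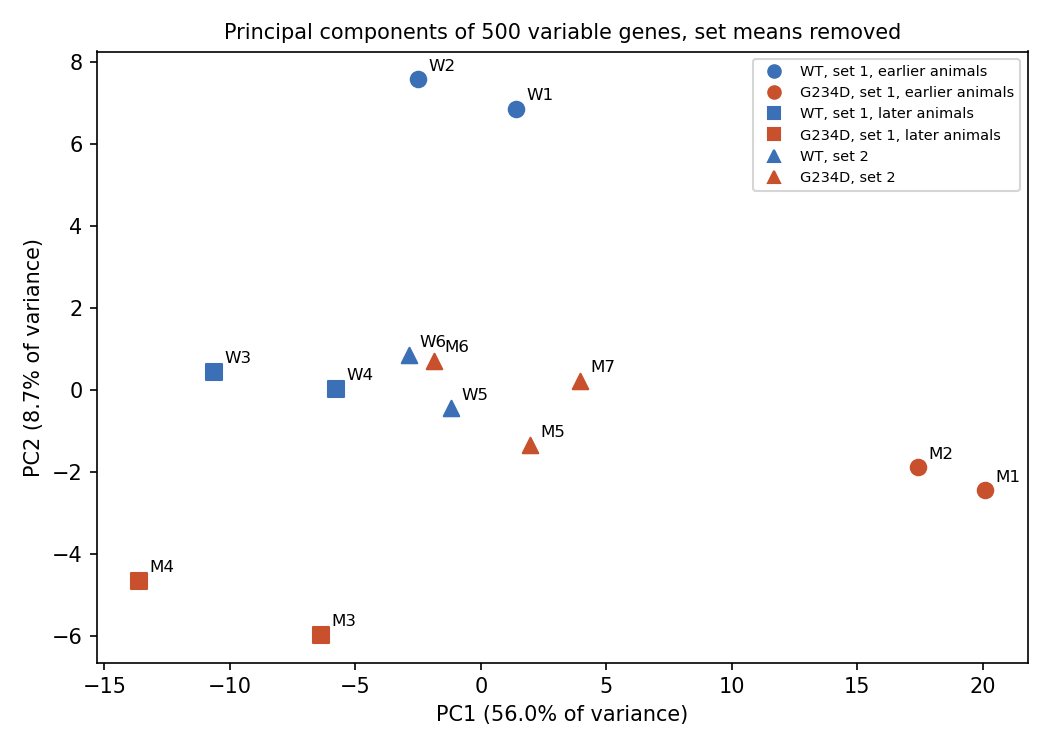
First 2 principal components (x axis 56.0% and y axis 8.7% of the variance) of the 500 most variable genes after removal of each set's mean, 1 point per culture. M1 (20.1) and M2 (17.4) lie apart on the first component, on which the other 11 cultures lie between −13.6 and 3.96.

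Set 2 asked the same question in separate animals. Ribosomal protein genes shifted downward (mean −0.067, adjusted p = 8.1e-12, and adjusted p = 0.934 with an estimated correlation), with Rpl24 at −0.11, as did oxidative phosphorylation genes (mean −0.040, adjusted p = 1.9e-04, and adjusted p = 0.934 with an estimated correlation) and interferon genes (mean −0.056, adjusted p = 0.0290, and adjusted p = 0.934 with an estimated correlation). Muscle genes (mean 0.42, adjusted p = 2.9e-04), macrophage genes (mean 0.30, adjusted p = 0.00386) and genes of the unfolded protein response (mean 0.078, adjusted p = 0.0299) shifted upward, each with an adjusted p of 0.934 with an estimated correlation. Without M5 the adjusted p was 0.111 for muscle, 0.185 for macrophage and 0.185 for unfolded protein response genes, and without W5 it was 0.227 and 0.622 for the latter 2. Without M7 it was 0.0599 for the unfolded protein response and 0.0924 for oxidative phosphorylation, and without W6 0.185 for oxidative phosphorylation and 0.982 for interferon genes, which turned upward without M6 (0.404).

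Of 12060 genes in set 2 limma called 1, with 781 at unadjusted p under 0.05, 510 higher and 271 lower. This gene was Gm45837 (ENSMUSG00000030653, plus strand of chromosome 7 from 101410886 to 101512819), which lies outside the rule for named genes and is named after its values were seen. It stood at 0.0782 ± 0.0596 TPM in WT (SD, n = 2) and 5.78 ± 1.82 TPM in G234D cultures (SD, n = 3), a difference of 2.62 (SE 0.23, adjusted p = 0.0125). Its annotated span overlaps that of Pde2a, a phosphodiesterase gene on the same strand, which stood at −1.15 (SE 0.23, adjusted p = 0.617), and at its start that of Arap1 (−0.049, SE 0.057, same strand), so the division of reads among these gene models is uncertain. In set 1 Gm45837 ranged from 0 to 6.64 TPM in WT and from 0.026 to 4.18 TPM in G234D cultures. Without W5 or without W6, where the lone WT culture was assumed to vary like the others, 0 genes were called, while 14 genes were called without M6, 2 without M7 and 21 with the replicate numbers as a block.

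The sets were then compared directly. Ddx3y was expressed in W1, M1, M2, M3 and W3 of set 1 and in no culture of set 2, so the sets also differed in Y-linked expression. By the test of set by genotype limma called 0 of 11942 genes, with 691 at unadjusted p under 0.05. The lists with the smallest p in that test were cholesterol synthesis, −0.16 in set 1 and 0.070 in set 2 (adjusted p = 1.4e-07), interferon response, 0.31 and −0.056 (1.4e-06), and ribosomal protein genes, 0.016 and −0.067 (5.7e-06); the adjusted p was 0.812 for each with an estimated correlation, and that of the ribosomal list was 0.412 without M4. Across 11797 genes, which are not independent replicates, the differences of the 2 sets correlated with a Pearson coefficient of 0.103 (exact permutation p = 0.489, two-sided, over 700 relabelings of the cultures) and a Spearman coefficient of 0.034 (exact permutation p = 0.800), with an adjusted p of 0.800 for both. The sign was shared by 49.1% of genes. Without M1 and M2 the Pearson coefficient was −0.135, and between the earlier animals of set 1 and set 2 it was 0.166, against −0.0817 between the later animals and set 2.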

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

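Of the tests below, those on cells of other types in M1 and M2, on sex among cultures with Y-linked expression, on M1 and M2 alone, on a genotype effect common to both sets, by animal number and the intervals over cultures were chosen only after the result was seen. Among 79 genes and 38 lists in 2 groups of 4 cultures, 12 had 1 culture far from the other 3, where chance gives about 1 in 20 (11.7).

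Muscle, macrophage and glial marker lists were higher on average in G234D cultures. Sex alone did not set M1 and M2 apart, since they lay 1.45 (95% interval 0.97 to 1.93) above W1, W3 and M3, which also have Y-linked expression. M1 and M2 were picked as highest on these lists, so that interval is no independent test. Over both sets the mean difference was 0.58 (95% interval over cultures −0.056 to 1.21). With Y-linked expression as a covariate it was 0.49 (−0.13 to 1.11), or 84.3% of it. Both intervals include 0, so the covariate does not decide on sex. Cells of other types in M1 and M2 are a candidate explanation. Of 15 marker transcripts of these lists, ranked by their level in the other cultures, 11 had their 2 highest values in M1 and M2. The lists are those on which M1 and M2 were picked as highest, so this count is no independent test either. The exceptions were Mitf and the macrophage genes C1qa, C1qb and C1qc, with C1qa at 15.7 TPM in M5 and 11.9 TPM in M1. Without M1 and M2 the set 1 mean of the muscle list went from 0.88 to −0.22, and 36.6% of the glial difference of set 1 was left. Over both sets the muscle list stayed upward without M1 and M2 (camera adjusted p = 0.736). A genotype effect in every G234D culture stays open, since the mean of the 3 lists lay above every WT culture of the set in 6 of 7. The exception was M4 at 2.01, below W1 (2.29) and W4 (2.24) and above W2 (1.98) and W3 (1.96). M3 (2.32) lay little above W1. Cells of other types in M1 and M2 and a genotype effect cannot be told apart.

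Ribosomal protein and oxidative phosphorylation genes shifted downward in set 2, though M5 lay at 0.011 above the WT mean for the latter. Transcript length bias stays open. The ribosomal list lay at −0.061 relative to genes of like annotated length, with a 95% bootstrap interval over genes, not cultures, of −0.072 to −0.050. That length merges the exons of all isoforms (median 1805.5 bases for the list) and need not be that of the expressed transcript. Over genes outside these 2 lists, length and the set 2 difference had a Spearman coefficient of 0.255. A genotype effect in both sets stays open, since the set 1 mean of 0.016 joined −0.093 in the earlier and 0.13 in the later animals and was −0.056 without M4. A single library stays open too: without W6 46.5% of the difference was left, and W6 is 1 of only 2 WT cultures.

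Proliferation and cholesterol synthesis genes were lower and interferon genes higher on average in the G234D cultures of set 1. For interferon genes the values that M1 and M2 alone would give were there, with a difference in the later animals of −1.64% of that in the earlier ones. The 95% interval of that difference over the later cultures ran from −0.38 to 0.36, so a smaller one there is not excluded. For cholesterol genes the share in the later animals was 159% and for proliferation genes 15.6%. Without M1 and M2 102% of the set 1 difference of proliferation genes was left, but that sets later G234D cultures against WT cultures of both animal groups. Both lists stay open, since the 95% intervals in the later animals ran from −0.77 to 0.39 and from −0.30 to 0.25. A genotype effect common to both sets stays open: 3 of 3 lists had a set 2 mean of the other sign or under 0.25 of that in set 1, but the intervals of the difference between the sets all included 0 (cholesterol −0.054 to 0.51). Dilution of fibroblasts by other cells cannot be told apart from lower expression: the fall in M1 and M2 over that of the fibroblast identity list was 0.448 for proliferation and 1.09 for cholesterol genes, and in the later animals cholesterol genes were at −0.19 and the identity list at 0.031, from 2 cultures of each genotype.

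For the counts of called genes the splits say nothing on chance, since any split reaches the real 0: 100 of 100 over both sets (highest other 1) and 35 of 35 in set 1 (highest other 671). Chance could not be excluded for the other counts over all splits, some of which follow the animal numbers. Over both sets 19 of 100 splits had as many at unadjusted p under 0.05 (real 769, highest other 2137) and 34 had as many lists (real 10, highest other 17). In set 1 10 of 35 had as many at unadjusted p under 0.05 (real 721, highest other 2958) and 9 had as many lists (real 12, highest other 16). The split with 671 called genes set W1, W2, M1 and M2 against W3, W4, M3 and M4, the order of the animal numbers, and shows a structure of the samples; with these groups as a block limma called 1 gene in set 1. Of the 18 splits of set 1 balanced over these groups, 2 had as many genes at unadjusted p under 0.05 (highest other 903) and 3 as many lists (highest other 14). These counts include the real split, and 18 splits are too few for a share under 0.05. Within the earlier animals genotype gave 3161 genes at unadjusted p under 0.05 (highest other 126) and within the later animals 1071 (highest other 413), from 3 splits each, again too few.

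In set 1 the following cultures lay apart from the other 3 of their group. Shkbp1 was at 30.0 TPM in M1, Mfap3 at 26.7 TPM in M3, Efemp1 at 66.5 TPM in M1, P4ha2 at 144 TPM in M4 and Gpc6 at 58.8 TPM in M3. Myh8 was at 1.22 TPM in W1, Ndufa3 at 166 TPM in M2 and Btg2 at 61.1 TPM in W3. Relative to the WT mean of the set, the other collagens were at 0.073 in W3, the unfolded protein response at 0.041 in W1, hypoxia and glycolysis at −0.21 in M4 and macrophage genes at 0.55 in W1.

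The genotype difference differed between the sets for 9 lists by the interaction, each with an adjusted p of 0.812 with an estimated correlation. The adjusted p was 1.4e-07 for cholesterol synthesis, 1.4e-06 for interferon response and 2.3e-04 for melanocyte and Schwann cell genes. It was 5.7e-06 for ribosomal proteins (0.412 without M4) and 5.5e-04 for oxidative phosphorylation (0.112 without M7, 0.136 without W6). It was 0.00933 for proliferation (0.111 without W1, 0.0880 without M3, 0.119 without M5) and 0.00933 for reticular fibroblasts (0.0559 without M6, 0.0899 without W5). It was 0.0308 for skeletal muscle (0.452 without M1, 0.244 without M2, 0.0676 without W2, 0.0740 without W3, 0.122 without M6, 0.0737 without W5, 0.0806 without W6). It was 0.0491 for matrix proteases (0.278 without M1, 0.174 without M2, 0.0534 without W2, 0.147 without W4, 0.146 without M5, 0.113 without M6, 0.111 without W5, 0.0789 without W6).

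Y-linked genes were seen at low levels in M4, with Ddx3y at 0.0949, Uty at 0.0187, Kdm5d at 0.0330 and Eif2s3y at 0.478 TPM, against 0 in the other libraries without Y-linked expression.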

How the results depend on the processing

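Of these alternatives, the pseudocounts, the scalings, no trend, array weights, the block of 2 animal-number groups and the fits without M1 and M2 were chosen after seeing the data. Fbn1 kept its positive difference without a call in all 16 alternatives (0.12 to 0.17) and all 13 left-out libraries (0.12 to 0.18). No gene of the 79 examined changed direction, though no difference of Col1a1 was left after quantile normalization, by construction at an unchanged rank. Of the 79 genes 11 moved by over 1.5 times with 1 library left out. The sign was the same in the earlier animals, the later animals and set 2 for 60 of them. Most of the 79 were picked by a small p over both sets, which in itself favours a stable sign. Over all 11797 genes compared, 49.1% shared a sign between the sets. Over both sets 0 genes were called in all alternatives but 1: the inverse-variance mean of the sets called 130. That mean takes the SEs as known, uses a normal approximation and weights each set by its own SE. Whether these account for the count was not tested. In set 1 the replicate block, the animal number block and the block of 2 animal-number groups called 1 gene each (Col7a1, but another gene with the animal number block), array weights 42 and the fit without M1 and M2 23; left-out libraries gave 0 to 2. In set 2 the count was 0 with no filter, a stricter filter, a pseudocount of 5 or no trend, and 21 with the replicate block; left-out libraries gave 0 to 14. In the interaction it was 2 with array weights and 16 without M1 and M2; left-out libraries gave 0 to 1. The count of lists was 6 with the stricter filter over both sets and 6 in set 1, where fewer genes were tested. It was 0 over both sets, in set 1 and in set 2 with an estimated correlation and by fry. Left-out libraries gave 7 to 12, 10 to 14 and 4 to 9. A form of fry in which members may move either way had lowest adjusted p values of 0.566, 0.0220 and 6.9e-04. It does not say that a list moved 1 way. The correlation of the sets was −0.135 without M1 and M2 and 0.0049 to 0.192 with 1 library left out. With the replicate block 9, 15 and 7 lists passed over both sets, in set 1 and in set 2, and over both sets and in set 1 no list call changed but those already given. Lists gained a call with no filter (Hox and Tbx 0.0430), the stricter filter (reticular 0.0363), median-of-ratios scaling (chemokines 0.0292, oxidative phosphorylation 0.0371), quantile normalization (collagen processing, p53, chemokines, unfolded protein response and reticular, each 0.0498) and without M1 and M2 (integrins 0.00227, YAP 0.00149, oxidative phosphorylation 0.0253, pericyte 9.2e-04). Lists that turned direction had these adjusted p values. With no filter they were 0.958 (other collagens) and 0.631 (keratinocyte), with the stricter filter 0.896 (TGF-beta ligands, Hedgehog, Notch and FGF, papillary), and with the replicate block 0.799 (microfibril), 0.562 (hypoxia) and 0.948 (keratinocyte). With the Y-linked covariate hypoxia was at 0.590, with median-of-ratios scaling Hedgehog was at 0.939 and keratinocyte at 0.920, and with quantile normalization other collagens were at 0.989. Without M1 and M2 they were 0.924 (fibrillar collagens), 0.947 (other collagens), 0.315 (proteases), 0.0505 (p53), 0.0332 (interferon), 0.813 (chemokines), 0.260 (hypoxia), 2.5e-05 (ribosomal), 0.627 (dermal papilla) and 0.933 (fibroblast identity). By fry they were 0.959 (other collagens, keratinocyte, endothelial), 0.987 (TGF-beta ligands) and 0.907 (Hedgehog). With 1 library left out further lists turned in some of the 13 fits only. Their ranges over all 13 fits, turned or not, were 0.602 to 0.999 (Hedgehog), 0.303 to 0.957 (TGF-beta ligands) and 0.0802 to 0.872 (YAP). They were 0.125 to 0.952 (hypoxia), 0.240 to 0.993 (keratinocyte), 0.455 to 0.984 (microfibril) and 7.4e-11 to 0.898 (ribosomal). The ribosomal list turned only without M1 or without M2, and its lowest value, without M4, was downward. Where no construction is named, the cause was not tested. Fits without M1 and M2 set later G234D cultures of set 1 against its WT cultures of both animal groups. Differences between these groups can enter such fits. Fits with edgeR, DESeq2, voom or a surrogate variable need counts and were not run, the Y-linked covariate had no spread in set 2, and the depth behind low TPM is unknown.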

Other observations

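Both the division of set 1 by animal number and the tests in this part were chosen only after the result was seen. With genotype in the model, limma called 850 of 11905 genes between the later and the earlier animals of set 1, 332 higher and 518 lower in the later ones. Contractile and cytoskeletal genes were lower in 23 of 23 members, 15 of them called (mean −0.39, adjusted p = 5.1e-10, and adjusted p = 0.566 with an estimated correlation). Integrins were lower in 12 of 13 members, 4 of them called (mean −0.31, adjusted p = 0.00219, and adjusted p = 0.566 with an estimated correlation). Ribosomal protein genes were higher in 74 of 74 members, 39 of them called (mean 0.22, adjusted p = 2.7e-31, and adjusted p = 0.566 with an estimated correlation), and cholesterol synthesis genes in 25 of 28, 2 of them called (mean 0.14, adjusted p = 3.3e-06, and adjusted p = 0.701 with an estimated correlation). M1 and M2 are among the earlier animals, and muscle genes (mean −1.05, adjusted p = 0.00113), macrophage genes (−0.76, 0.00503) and interferon genes (−0.43, 0.00113) were lower and fibroblast identity genes higher (0.23, 0.00219) in the later ones, with adjusted p values of 0.724, 0.701, 0.741 and 0.495 with an estimated correlation.

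The single genes that follow were named after their values were seen. Prelp, a proteoglycan of the matrix, rose from 7.83 ± 1.71 to 27.5 ± 8.46 TPM (SD, n = 4 each) from the earlier to the later animals, and Fgf10, a growth factor of the mesenchyme, from 2.28 ± 0.214 to 5.51 ± 0.647 TPM. Tgfbr3, a TGF-beta co-receptor, rose by 0.76 (SE 0.067) on the log2 scale and Cyp26b1, which degrades retinoic acid, by 1.26 (SE 0.14). Tgfb2 fell from 21.4 ± 0.964 to 10.7 ± 1.86 TPM and the gelatinase gene Mmp9 from 8.53 ± 1.07 to 3.22 ± 1.21 TPM.

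Ddx3y, a Y-linked gene, was expressed in 5 of the 13 libraries (W1, M1, M2, M3 and W3), at 49.997 to 61.9 TPM.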
